A study of Mus musculus with 24 samples.

How the data were processed

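Total RNA from the distal and proximal parts of the mandible and maxilla of mouse embryos at embryonic day 14.5 was isolated with a column kit. From each sample, 5 µg were made into biotin-labelled cRNA and hybridised to a single-colour mouse oligonucleotide array, per the labels. There were 24 arrays in 8 groups of 3, from Wnt1-Cre mutants for Alk5 and control littermates on a C57B6 background. The deposited values are log2 signals that the authors made by RMA normalization, per the submitters' processing notes, with no RMA version given. The base of the logarithm is not written there, and log2 was read from the range of 3.29 to 14.86. The table held 45101 probe sets, no detection calls and no probe coordinates, so no genome positions are given.

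Gene symbols were taken from the array annotation. Of the probe sets, 34945 were assigned to exactly 1 symbol, 932 to several, 9160 to none, and 64 were controls. A RefSeq table of mouse assembly GRCm38.p6, used for names only, matched 34741 of the probe sets with 1 symbol by gene identifier and changed 0 symbols. Each of 18193 genes was represented by its probe set with the highest mean over all arrays, and 9010 genes had more than 1 probe set. A gene was tested when its probe set lay above the 40th percentile of the array in at least 3 arrays (a log2 level of 6.33 to 6.47), which 13942 genes met.

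A linear model with 1 mean per group was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3, with moderated statistics from eBayes with a mean-variance trend and Benjamini-Hochberg adjustment over the genes of each comparison. Genes at an adjusted p under 0.05 were called. All p-values from limma and camera are two-sided. There were 10 comparisons: mutant against control in each of the 4 regions, the mean of those 4 differences, the difference of the genotype effect between the jaws and between the ends, mandible against maxilla in controls, and distal against proximal in the control mandible and maxilla. Errors on log2 changes are standard errors of the fit, and errors on group levels are standard deviations of 3 arrays. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

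The groups, the comparisons, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined, except where stated otherwise. The named genes are those past the threshold with the largest change, 10 in each direction for the mean genotype effect and the jaw comparison and 5 in each direction otherwise. In comparisons within a region or jaw the arrays of the groups also had to lie apart, and in the mean effect and the jaw comparison the sign had to be the same in every region or end. Unnamed transcript symbols, Y-linked genes and Xist were passed over. Up to 4 members with the largest absolute moderated statistic were eligible as examples for each list. The examples given mostly kept their call whichever single array was left out. That choice was made after the values were seen, so they are steadier than the other eligible members. Tgfbr1, Tgfbr2, Tgfb1, Tgfb2 and Tgfb3 were always named.

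Of 32 lists of marker and pathway genes written from general knowledge, those with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation was an alternative, and fry was also run, which asks whether the members of a list move one way on balance. The lists of salivary gland genes (1 of 7 measured), Hox genes (4 of 11) and sex-linked genes (4 of 5) were too small and were not tested. With the preset correlation 11, 8, 10 and 10 lists were called in the distal mandible, distal maxilla, proximal mandible and proximal maxilla, 9 in the mean effect, 11 and 8 in the jaw and end interactions, 16 between the jaws, and 7 and 11 between the ends of the control mandible and maxilla. With an estimated correlation 1, 2 and 4 were called in the last 3 and 0 in the others. By fry the numbers were 15, 6, 11, 10, 12, 3, 2, 22, 5 and 10 in the order given.

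The labels give each array a replicate number from 1 to 3. Whether the numbers pair arrays was checked by correlating the residuals of arrays with the same number across genes, which are not independent replicates. The lowest r of the 3 numbers was 0.14 in the distal mandible, 0.19 in the proximal mandible, 0.21 in the distal maxilla, 0.28 in the mean over regions and 0.27 in the control mandible. It was 0.24 between the mutant jaws, 0.26 in the mutant mandible and 0.58 in the mutant maxilla. The 3 values were 0.25, -0.13 and -0.18 in the proximal maxilla, 0.36, 0.19 and 0.06 between the control jaws, and 0.25, 0.11 and 0.01 in the control maxilla, where not every r was over 0.1.

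Alternatives were quantile normalization of all arrays again, limma array weights, no filter and a filter at the 60th percentile (11079 genes), and a log2 change of at least 1. The replicate number was used as a fixed block, as a random block within genotype (consensus correlation 0.231) or through averaging the 4 regions of a number. Others were the mean of the probe sets of a gene, each probe set on its own, leaving out each array, only the arrays of the groups compared, a sex score from Xist and Y-linked genes as a covariate, and eBayes with robust priors or without a trend. Leaving out both mutant maxilla arrays numbered 3, and lists of ciliated, cornified, olfactory, muscle precursor and muscle contractile genes, were added after the data were seen. The fit was tested on 13942 simulated genes with 50 changed at each of 4 sizes. At a log2 change of 1 it recovered 90% in the distal mandible, 82% in the distal maxilla, 86% in the proximal mandible, 84% in the proximal maxilla and 96% in the mean effect. Over all sizes 8 of 184, 20 of 193, 7 of 177, 7 of 179 and 5 of 201 calls were false. This does not check the real counts, where arrays of a number correlated (0.231).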

Results

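RNA from mouse jaws at embryonic day 14.5 was measured on 24 arrays. The mutant embryos carried floxed alleles of Alk5, the type I receptor for TGF-beta whose gene symbol is Tgfbr1, and the Wnt1-Cre driver, which recombines in the cranial neural crest lineage that forms most of the facial skeleton. Per the design text, mutants were recognised by a cleft palate and a defect of the calvaria. Mandible and maxilla were each separated into a distal and a proximal part, and the labels name the compartment of each part as bone. Genotype, jaw and end gave 8 groups of 3 arrays. Array medians lay between 7.03 and 7.12 on the log2 scale, and the mean correlation of an array with the other arrays of its group lay between 0.9688 and 0.9943. Levels under the filter level of 6.33 to 6.47 were read as background. Against a group mean under it the size of a log2 change is a lower limit, and folds are given only where the levels of both groups lay above it. With 3 arrays per group, the number of arrays limits the precision. The labels do not say that the arrays of a group came from separate embryos, so the p-values measure only the spread between these arrays. Part of it may be technical, but the sex markers given next differ within every group, so its arrays were not all repeats of the same RNA.

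Tgfbr1, the targeted gene, was higher in the mutant by 0.26 ± 0.04 (log2 change ± SE, mean of 4 regions, 12 arrays per genotype, 1.19-fold, limma adjusted p = 0.000146), and all 3 of its probe sets were higher, by 0.56, 0.55 and 0.26. Its mean level was 12.15 in controls and 12.41 in mutants. The probe sets may lie outside the deleted part of the gene and only cells of the Wnt1-Cre lineage lose it, so these values check nothing about the labels. Xist, the RNA that silences an X chromosome in female cells, and the Y-linked genes Eif2s3y, Kdm5d and Uty were read as a record of the sex of the embryos. In the controls, the arrays with replicate number 1 had Xist at 13.53 to 13.67 in the 4 regions and the arrays numbered 2 and 3 had Xist at 6.23 to 7.49. Among the mutants, the arrays numbered 2 had Xist at 13.03 to 13.39, and those numbered 1 and 3 showed both Xist, at 11.15 to 12.79, and Y-linked transcripts, at 8.51 to 10.01. These arrays may hold pools of embryos of both sexes, which the labels do not state, and the SD, SE and n of mutants would then refer to pools. As signals of RNA quality, the 3' minus 5' difference of the control probe sets was 0.122 ± 0.023 in controls and 0.1 ± 0.022 in mutants for Actb (SD, n = 12), -0.41 ± 0.028 and -0.43 ± 0.036 for Gapdh, and 1.41 ± 0.112 and 1.52 ± 0.119 for pyruvate carboxylase. Mutant proximal maxilla 3 had the highest value of the latter, 1.81.

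**Figure D1:**
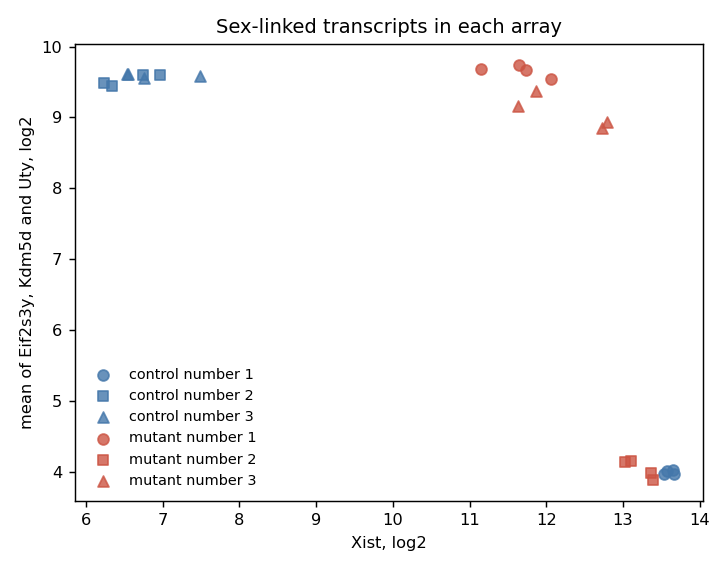
The mean of Eif2s3y, Kdm5d and Uty (vertical axis, log2) against Xist (horizontal axis, log2) for each of the 24 arrays, by genotype. The mutant arrays numbered 1 and 3 lie at high values of both, with Xist from 11.15 to 12.79.

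The ligands and receptors of TGF-beta moved apart in the mutant. Tgfb2 was higher in every region, by 0.36 ± 0.11 in the distal mandible (SE, n = 3 per genotype, adjusted p = 0.0287), 0.72 ± 0.11 in the distal maxilla (0.0019), 0.99 ± 0.11 in the proximal mandible (8.41e-06) and 0.83 ± 0.11 in the proximal maxilla (0.000104), and all 4 of its probe sets had that sign. Tgfb3 fell by 1.16 ± 0.15 in the distal mandible (6.56e-05) and fell by 0.76 ± 0.15 in the proximal mandible (0.00143), and Tgfb1 fell by 1.38 ± 0.29 in the proximal mandible (0.00228). In the distal maxilla the log2 changes of Tgfb1, 0.08, and Tgfb3, 0.077, did not pass the test and changed sign under other settings. Over the mean of the 4 regions the log2 change was 0.72 ± 0.05 for Tgfb2 (2e-08), -0.53 ± 0.08 for Tgfb3 (1.96e-05), -0.51 ± 0.15 for Tgfb1 (0.00859) and -0.26 ± 0.05 for Tgfbr2, the type II receptor (0.000366). By region, Tgfbr1 changed by 0.22 in the distal mandible (adjusted p = 0.101, and 0.0112 with the replicate number as a block), 0.38 in the distal maxilla (0.0298), 0.33 in the proximal mandible (0.0115) and 0.10 in the proximal maxilla (0.513). The call of Tgfb2 in the distal mandible ended without control array 2 or 3 or mutant 1 or 3 (0.30 to 0.34, adjusted p from 0.0809 to 0.11). That of Tgfbr1 in the distal maxilla ended without control 3, mutant 1 or mutant 2 (0.30 to 0.35, 0.0991 to 0.173). That of Tgfbr1 in the proximal mandible ended without control 2 (0.29, 0.0621). That of Tgfbr2 in the distal mandible (-0.38 ± 0.10, 0.0122) ended without mutant 2 (-0.31, 0.0814). With the 4 regions of each replicate number averaged first, as a block, the mean changes of Tgfbr2 (adjusted p = 0.0508) and Tgfb1 (0.0967) did not pass. With only the arrays compared, Tgfb2 (0.0845) and Tgfbr1 (0.282) did not pass in the distal maxilla, nor with the mean of probe sets Tgfbr1 in the proximal mandible (0.058) or Tgfbr2 in the distal mandible (0.0667).

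The genotype effect averaged over the regions took arrays of a replicate number as independent. They correlated (0.231), so p-values for genes and lists may be too low. Genes of the skeletal matrix led the fall: Dmp1, a protein of mineralising bone and dentin matrix, went from a mean of 10.80 in controls to 6.85 in mutants (-3.96 ± 0.61, SE, 12 arrays per genotype, adjusted p = 4.55e-05). Mmp13, the collagenase of hypertrophic cartilage and bone, fell by 3.93 ± 0.81 (0.000732). C1qtnf3, a secreted protein made by cartilage, fell by 3.62 ± 0.23 (4.76e-09). The cartilage matrix genes Matn3 (-3.28 ± 0.32), Matn1 (-3.05 ± 0.51), Comp (-3.01 ± 0.31), Epyc (-2.83 ± 0.39), Snorc (-2.70 ± 0.31) and Col11a2 (-2.45 ± 0.28), and Col22a1, a collagen of the muscle-tendon junction (-2.40 ± 0.34), fell as well. Among genes with the same sign in all 4 regions, the largest rise was that of the homeobox gene Hoxd1 (1.99 ± 0.34, adjusted p = 0.000112), followed by Cbln4, a synaptic organiser (1.49 ± 0.21), Nnat, an imprinted gene of the endoplasmic reticulum (1.44 ± 0.12, adjusted p = 6.63e-08), Hey2, a Notch target (1.37 ± 0.15), and Avpr1a, a vasopressin receptor (1.37 ± 0.11). Insyn2b (1.29 ± 0.15), Arg1, an arginase (1.25 ± 0.31), Sned1 (1.21 ± 0.10), Gata3, a transcription factor (1.15 ± 0.15), and Unc5d, a netrin receptor (1.14 ± 0.19), rose as well. Cxcl14, added after its values were seen, rose more (2.08 ± 0.21, adjusted p = 5.33e-07) but was at -0.18 in the distal maxilla. Of the 20 genes before it, C1qtnf3, Matn3, Nnat and Sned1 passed in each of the 4 regions. Hoxd1 lay under the filter level in the distal mandible of both genotypes and Cbln4 in the distal maxilla.

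Among the gene lists, cartilage genes had 16 of 19 measured members lower (17 adjusted over the list alone, median log2 change -1.76, camera adjusted p = 1.91e-10). Bone genes had 12 of 15 lower (13 adjusted over the list alone, median -1.06, 2.86e-08), with Omd, a keratan sulfate proteoglycan of bone, at -1.71 ± 0.21. Both had adjusted p = 0.266 with an estimated correlation. Tendon genes had 9 of 10 lower (9 adjusted over the list alone, median -1.17, 4.59e-09), among them Fmod, a small proteoglycan (-2.02 ± 0.15). Osteoclast genes had 6 of 7 lower (6 adjusted over the list alone, median -1.22, 2.43e-06), led by Atp6v0d2, a proton pump subunit (-1.70 ± 0.12). Macrophage genes, a marker set of another cell type, had 8 of 14 lower (9 adjusted over the list alone, median -0.43, 0.000661), with Ptprc, the pan-leukocyte antigen, at -0.77 ± 0.11. Muscle genes had 8 of 25 lower (8 adjusted over the list alone, median -0.49, 0.000661), including muscle creatine kinase Ckm (-1.58 ± 0.20). The last 4 had adjusted p = 0.096, 0.133, 0.612 and 0.808 with an estimated correlation.

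Genes induced by TGF-beta in mesenchymal cells had 11 of 17 members lower and 2 higher (12 and 2 adjusted over the list alone, median -0.35, camera adjusted p = 1.4e-05). Pmepa1, a feedback inhibitor of the pathway, fell by 0.62 ± 0.05. The matricellular genes Ccn1 and Ccn2 changed by -0.99 ± 0.08 and -1.34 ± 0.13, while Tgif1, a corepressor, rose by 0.53 ± 0.05. Wnt response genes had 7 of 11 higher and 2 lower (7 and 2 adjusted over the list alone, median 0.46, 0.0123), with the transcription factor Lef1 at 0.82 ± 0.06. Maxilla and palate genes had 8 of 11 higher and 1 lower (8 and 1 adjusted over the list alone, median 0.66, 0.00501), with the odd-skipped factor Osr1 at 1.03 ± 0.11. These 3 had adjusted p = 0.096, 0.269 and 0.171 with an estimated correlation. The other 20 lists did not pass. Their medians and adjusted p were, for signalling, -0.012 and 0.753 (TGF-beta pathway), 0.23 and 0.159 (BMP response), 0.038 and 0.622 (hedgehog response), and -0.055 and 0.649 (FGF response). For tissues they were 0.038 and 0.903 (tooth), 0.31 and 0.163 (epithelium), -0.029 and 0.165 (endothelium), 0.16 and 0.898 (erythroid cells), 0.086 and 0.898 (neurons), 0.18 and 0.603 (glia), -0.068 and 0.898 (brain, eye and olfactory), and 0.15 and 0.113 (cranial mesenchyme). For identity they were -0.036 and 0.834 (mandible), 0.31 and 0.101 (distal jaw), and 0.28 and 0.386 (proximal jaw). The remaining values were -0.030 and 0.488 (proliferation), 0.076 and 0.973 (p53 targets), 0.044 and 0.898 (immediate early genes), 0.072 and 0.985 (hypoxia), and -0.003 and 0.903 (lipid metabolism).

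In all, 5655 of 13942 genes differed in the mean of the 4 regions, 3519 higher and 2136 lower (62.2% higher). Of the 158 with a log2 change of at least 1, 28 were higher and 130 lower (17.7% higher). With the 4 regions of each replicate number averaged first, 2114 genes passed (1099 higher, 1015 lower), and Mmp13 had adjusted p = 0.0576. No list was tested this way. In all 4 regions 86 genes were higher and 32 lower, and 47 genes were higher in 1 region and lower in another.

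**Figure D2:**
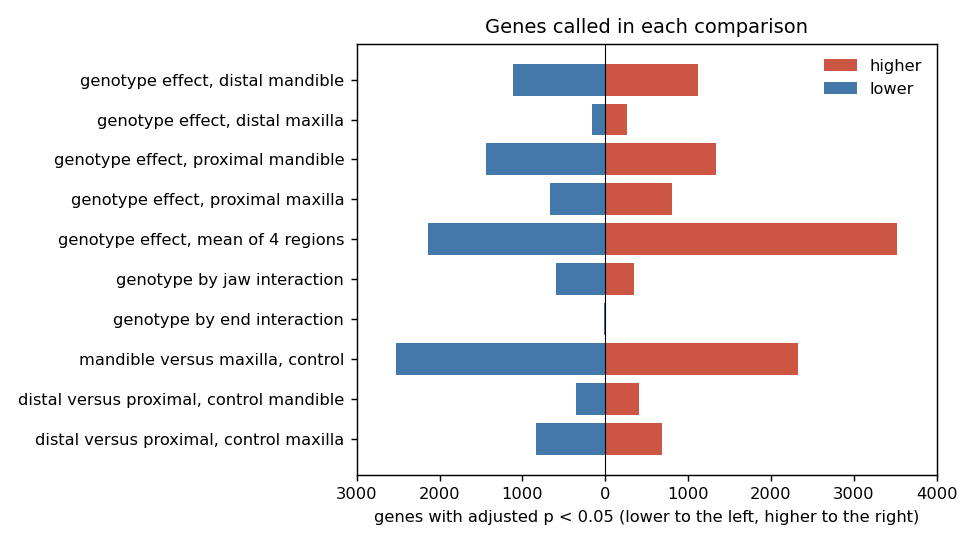
Bars show the number of genes (horizontal axis) higher or lower at a limma adjusted p under 0.05 in each comparison (vertical axis), of 13942 genes tested. The genotype effect was called for 2777 genes in the proximal mandible and for 413 in the distal maxilla.

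In the distal mandible, Dmp1 went from 11.45 ± 0.26 in controls to 5.11 ± 0.05 in mutants (SD, n = 3), a change of -6.34 ± 1.22 (SE, adjusted p = 0.00169). Mmp13 changed by -5.98 ± 1.62 (0.0156), C1qtnf3 by -4.94 ± 0.47 (3.53e-06), the perinatal myosin heavy chain Myh8 by -4.29 ± 0.73 (0.000683) and Tceal7 by -4.21 ± 0.66 (0.000354). Hey2 rose from 7.94 ± 0.24 to 10.65 ± 0.24 (2.71 ± 0.29, 6.55-fold, adjusted p = 1.12e-05). The homeobox gene Emx2 (2.55 ± 0.33), Cbln4 (2.54 ± 0.42), the Wnt antagonist Dkk4 (2.43 ± 0.31) and the neural crest transcription factor Tfap2b (2.40 ± 0.26) rose too. In this region 2231 genes differed, 1118 higher and 1113 lower, and 4268 with array weights. Without control array 3 the count was 1330 and without mutant 2 it was 1243. The call of Mmp13 ended without control 3, mutant 1 or mutant 2 (-5.77 to -5.44, adjusted p from 0.0576 to 0.0703).

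**Figure D3:**
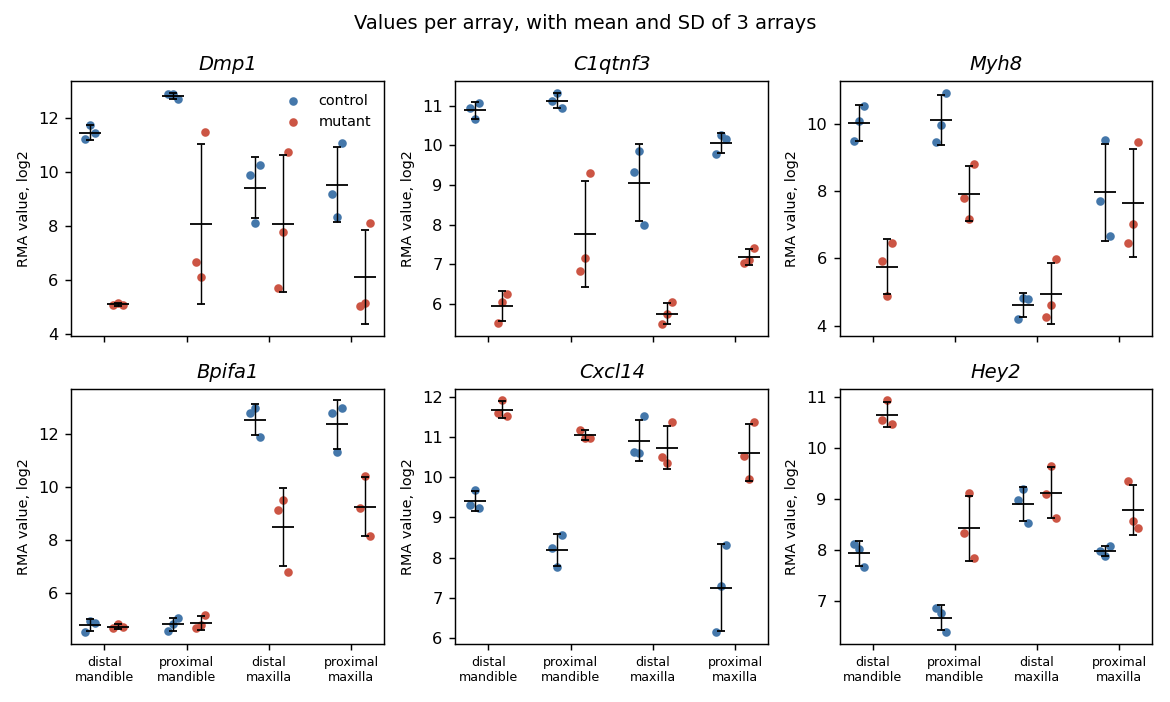
Log2 level (vertical axis) of Dmp1, C1qtnf3, Myh8, Bpifa1, Cxcl14 and Hey2 in each array, by region and genotype (horizontal axis), with the mean and SD of the 3 arrays. Dmp1 in the distal mandible averaged 11.45 in controls and 5.11 in mutants.

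Of 25 muscle genes, 13 were lower in the distal mandible (22 adjusted over the list alone, median -1.80, camera adjusted p = 1.68e-12), such as Ckm (-3.20 ± 0.41). Of 19 cartilage genes, 12 were lower (15 adjusted over the list alone, median -2.31, 1.28e-10), such as Matn3 (-4.12 ± 0.65). Of 15 bone genes, 13 were lower (13 adjusted over the list alone, median -1.23, 4.55e-10), such as Omd (-2.24 ± 0.41). Of 10 tendon genes, 8 were lower (8 adjusted over the list alone, median -1.48, 1.3e-11), such as Thbs4 (-3.68 ± 0.37). Osteoclast genes had 5 of 7 lower (6 adjusted over the list alone, median -1.67, 3.23e-07), including Atp6v0d2 (-2.39 ± 0.24). Macrophage genes had 5 of 14 lower (6 adjusted over the list alone, median -0.63, 3.18e-07), including Csf1r, the M-CSF receptor (-1.28 ± 0.20). Targets of TGF-beta had 10 of 17 lower and 1 higher (the same numbers adjusted over the list alone, median -0.43, 2.27e-06), with fibronectin Fn1 at -0.80 ± 0.12 and Tgif1 at 0.65 ± 0.10. Endothelial genes had 3 of 12 lower (3 adjusted over the list alone, median -0.10, 0.0183). Wnt response genes had 6 of 11 higher (7 adjusted over the list alone, median 0.71, 4.09e-05), with Lef1 at 1.14 ± 0.12. BMP response genes had 4 of 11 higher (5 higher and 1 lower adjusted over the list alone, median 0.32, 0.0201), with Id1 at 0.78 ± 0.06. Distal jaw genes had 2 of 6 higher (3 adjusted over the list alone, median 0.53, 0.0201), with the homeobox gene Alx4 at 0.62 ± 0.11. With an estimated correlation no list was called here: adjusted p = 0.258 for muscle, 0.246 for cartilage, 0.164 for bone, 0.0535 for tendon and 0.0757 for osteoclast genes. It was 0.278 for macrophage, 0.0638 for TGF-beta target, 0.475 for endothelial, 0.0757 for Wnt response, 0.446 for BMP response and 0.113 for distal jaw genes. Without mutant array 2 the medians of muscle and macrophage genes were -1.14 and -0.38, and that of endothelial genes was -0.17 without control 1 and -0.062 without control 3.

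In the distal maxilla, Bpifa1, a secreted protein of nasal and upper airway epithelium, went from 12.55 ± 0.59 to 8.47 ± 1.48 (SD, n = 3; -4.08 ± 0.58, SE, 16.9-fold, adjusted p = 0.00148). The retinaldehyde dehydrogenase Aldh1a1 fell by 3.42 ± 0.47 (10.7-fold, 0.00148), and Deup1, which builds centrioles in multiciliated cells, fell by 3.15 ± 0.47 (0.00189). C1qtnf3 (-3.30 ± 0.47, 0.00148) and Matn3 (-3.10 ± 0.65, 0.0156) fell here too. The palatal T-box gene Tbx22 (2.45 ± 0.53, adjusted p = 0.0204), Clca3a2 (2.15 ± 0.44, 0.015), the forebrain zinc finger gene Fezf2 (2.02 ± 0.31, 0.00222), the substance P precursor Tac1 (1.89 ± 0.30, 0.0023) and the synaptic adhesion gene Lrfn5 (1.63 ± 0.24, 0.00162) rose. In total 413 genes differed, 257 higher and 156 lower (62.2% higher), and after quantile normalization of all arrays 203 were higher and 204 lower (49.9%). With the replicate number as a block 1087 genes passed, with array weights 1194, with the sex score 242 and with only the arrays compared 23, where Tbx22, Bpifa1, C1qtnf3, Matn3 and Fezf2 did not (adjusted p from 0.0563 to 0.239). The count was 750 without control array 2, 111 without control 3, 47 without mutant 1, 162 without mutant 2 and 689 without mutant 3. Mutant array 3 correlated better with the mutant distal mandible (mean r = 0.976) than with its own group (0.9725), and without it and its proximal counterpart 1113 genes passed. Calls ended for Tbx22 without control 3 (2.05, adjusted p = 0.131), mutant 1 (1.95, 0.134) or mutant 2 (2.37, 0.0647), and without mutant 1 for Clca3a2 (1.92, 0.0932) and Matn3 (-3.33, 0.0563).

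In the distal maxilla cartilage genes had 1 of 19 lower (5 adjusted over the list alone, median -1.08, camera adjusted p = 0.000203). Tendon genes had 3 of 10 lower (4 adjusted over the list alone, median -0.41, 0.00132). Targets of TGF-beta had 4 of 17 lower and 1 higher (5 and 2 adjusted over the list alone, median -0.19, 0.00113), with Ccn2 at -1.67 ± 0.25. Oral and skin epithelium genes shifted by -0.44 (0.000203), although limma passed 0 of 19 members and 6 were lower at an unadjusted p under 0.05. These 4 had adjusted p = 0.658, 0.333, 0.284 and 0.411 with an estimated correlation. Osteoclast genes shifted by -0.45 (0.00138), with 0 of 7 members passed by limma, 2 adjusted over the list alone and 2 at an unadjusted p under 0.05. Immediate early genes shifted by -0.29 (0.0204), with 0 of 10 passed by limma and 4 lower and 1 higher at an unadjusted p under 0.05. Macrophage genes had 1 of 14 lower (3 adjusted over the list alone, median -0.27, 0.0204). BMP response genes had 2 of 11 higher (4 adjusted over the list alone, median 0.28, 0.00252). These 4 had adjusted p = 0.333, 0.284, 0.849 and 0.375 with an estimated correlation. In mutant array 3 of this region the genes of brain, eye and olfactory tissue had a median 0.98 below the other 2 arrays (-0.98), and bone and muscle genes lay 1.04 and 1.47 above. Without control array 3 the medians were 0.15 for BMP response (adjusted p = 0.0261), -0.34 for osteoclasts (0.0538), -1.97 for cartilage, -0.21 for macrophages (0.0507) and -0.19 for immediate early genes (0.0919). Without control 2 that of cartilage was -0.62 (0.0355). Without mutant 1 the call ended for macrophage (-0.19, 0.0653) and immediate early genes (-0.21, 0.0653). It ended without mutant 2 for macrophage genes (-0.12, 0.239) while tendon was at -0.17 (0.0146). Without mutant 3 the medians were -0.78 for osteoclasts, -0.64 for tendon, -0.68 for epithelium and -0.48 for macrophages. Leaving out both mutant maxilla arrays numbered 3 brought bone (-0.34, 0.000897), muscle (-0.39, 0.00642), neuron (1.15, 0.000357), glia (0.34, 0.0487), brain, eye and olfactory (0.30, 0.0278) and proximal jaw genes (0.63, 0.0129) past the threshold.

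In the proximal mandible, Hoxd1 went from 4.84 ± 0.14 to 8.91 ± 0.69 (SD, n = 3; 4.07 ± 0.67, SE, adjusted p = 0.000267). The epithelial chemokine Cxcl14 rose from 8.19 ± 0.40 to 11.04 ± 0.12 (2.85 ± 0.42, 7.23-fold, 9.16e-05), and the keratinocyte differentiation genes Krtdap (2.50 ± 0.57) and Krt1 (2.45 ± 0.41) and Cbln4 (2.50 ± 0.42) rose as well. Mmp13 (-4.78 ± 1.62, adjusted p = 0.0425), Dmp1 (-4.74 ± 1.22, 0.00879), the muscle-enriched gene Atp1b4 (-3.65 ± 0.41, 9.71e-06), Col22a1 (-3.46 ± 0.68, 0.0012) and Cgref1 (-3.38 ± 0.54, 0.000184) fell. Here 2777 genes differed, 1333 higher and 1444 lower (48% higher), and after quantile normalization of all arrays 1703 were higher and 1480 lower (53.5%). Mutant array 3 lay closer to the controls than to mutants 1 and 2 for Dmp1, at 11.48 against 6.66 and 6.10 (controls 12.69 to 12.89), and Mmp13, at 10.24 against 4.11 and 4.17 (controls 10.75 to 11.06). The call of Mmp13 ended without control 1, 2 or 3 (-4.89 to -4.73, adjusted p from 0.0918 to 0.0978), mutant 1 (-3.75, 0.162) or mutant 2 (-3.78, 0.177), with the sex score (0.0634), robust priors (0.056) or only the arrays compared (0.0618), and that of Dmp1 without mutant 2 (-3.75, 0.0607).

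Bone genes had 12 of 15 members lower in the proximal mandible (12 adjusted over the list alone, median -1.5, camera adjusted p = 1.75e-07), with the alkaline phosphatase Alpl at -1.80 ± 0.31. Osteoclast genes had 6 of 7 lower (6 adjusted over the list alone, median -1.78, 1.75e-07), with Atp6v0d2 at -2.99 ± 0.24. Tendon genes had 9 of 10 lower (9 adjusted over the list alone, median -1.55, 4.36e-10), with Aspn at -2.18 ± 0.22. Cartilage genes had 8 of 19 lower (9 adjusted over the list alone, median -1.02, 0.000251), with Col11a1 at -1.68 ± 0.35. Epithelial genes had 7 of 19 higher (8 adjusted over the list alone, median 0.83, 0.000198), with the splicing regulator Esrp1 at 1.06 ± 0.17. Macrophage genes had 6 of 14 lower (8 adjusted over the list alone, median -0.56, 0.000555), with Cd68 at -1.30 ± 0.24. Endothelial genes had 5 of 12 lower (5 adjusted over the list alone, median -0.21, 0.0041), with the VEGF receptor Kdr at -0.48 ± 0.10. Targets of TGF-beta had 9 of 17 lower and 1 higher (the same numbers adjusted over the list alone, median -0.36, 0.000107), with the urokinase receptor Plaur at -1.32 ± 0.12. Maxilla and palate genes had 5 of 11 higher (7 adjusted over the list alone, median 0.71, 0.0158), with Osr2 at 1.38 ± 0.25. Muscle genes had 2 of 25 lower (1 adjusted over the list alone, median -0.47, 0.0347), with Ckm at -2.52 ± 0.41. With an estimated correlation no list was called here: adjusted p = 0.358 for bone, 0.108 for osteoclast, 0.083 for tendon, 0.625 for cartilage and 0.565 for epithelial genes. It was 0.61 for macrophage, 0.565 for endothelial, 0.108 for TGF-beta target, 0.311 for maxilla and palate and 0.779 for muscle genes. The muscle call ended without control 3 (-0.18, adjusted p = 0.221) or mutant 2 (-0.054, 0.382) and its median was -0.76 without mutant 3. Without mutant 1 the endothelial median was -0.12 (0.0407) and the call of maxilla and palate genes ended (0.64, 0.0599).

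In the proximal maxilla, cartilage matrix genes led the fall. Comp went from 10.30 ± 0.18 to 6.39 ± 0.55 (SD, n = 3; -3.90 ± 0.61, SE, adjusted p = 0.000601), and Matn1 (-4.41 ± 1.02, 0.0097), Matn3 (-3.89 ± 0.65, 0.00101), Epyc (-3.56 ± 0.77, 0.0067) and Col11a2 (-3.54 ± 0.57, 0.000741) fell with it. Cxcl14 rose from 7.26 ± 1.08 to 10.61 ± 0.71 (3.35 ± 0.42, 10.2-fold, adjusted p = 8.01e-05), Krtdap by 2.75 ± 0.57 (0.00523), Krt1 by 2.70 ± 0.41 (0.000474), Them5 by 2.65 ± 0.54 (0.00447) and Hoxd1 by 2.60 ± 0.67 (0.0184). Here 1470 genes differed, 802 higher and 668 lower, against 2397 with the replicate number as a block and 320 with only the arrays compared, where Matn1, Epyc, Krtdap, Them5 and Hoxd1 did not pass (adjusted p from 0.0788 to 0.139). The count was 916 without control array 1, 733 without control 3 and 615 without mutant 3, and 783 without both mutant maxilla arrays numbered 3. Mutant array 3 correlated better with the mutant proximal mandible (mean r = 0.9811) than with its own group (0.9688). The call of Hoxd1 ended without control 3 (1.94, adjusted p = 0.108), mutant 3 (2.14, 0.106) or both arrays numbered 3 (0.0982) and with array weights (0.0587), and Matn1 was at -2.68 (0.0481) without mutant 3.

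Of 19 cartilage genes, 17 were lower in the proximal maxilla (17 adjusted over the list alone, median -2.97, camera adjusted p = 1.49e-16). Bone genes had 5 of 15 lower (8 adjusted over the list alone, median -0.90, 1.75e-05), such as the sialoprotein Ibsp (-3.50 ± 0.65). Tendon genes had 5 of 10 lower (5 adjusted over the list alone, median -0.54, 3.54e-05). Cranial mesenchyme genes had 4 of 11 higher (4 adjusted over the list alone, median 0.33, 0.000501), with the basic helix-loop-helix factor Twist2 at 2.26 ± 0.29. Maxilla and palate genes had 7 of 11 higher (7 adjusted over the list alone, median 0.87, 3.54e-05), with Osr1 at 1.73 ± 0.23. Wnt response genes had 5 of 11 higher (6 higher and 1 lower adjusted over the list alone, median 0.36, 0.00273), with Lef1 at 1.20 ± 0.12. Targets of TGF-beta had 5 of 17 lower and 2 higher (6 and 2 adjusted over the list alone, median -0.11, 0.00597), with Ccn2 at -1.79 ± 0.25. Osteoclast genes shifted by -0.54 (0.0227), with 0 of 7 members passed by limma, 4 adjusted over the list alone and 4 at an unadjusted p under 0.05. Genes of brain, eye and olfactory tissue shifted by -0.65 (0.0342), with 0 of 8 passed by limma and 5 at an unadjusted p under 0.05. Mandibular identity genes shifted by -0.43 (0.0311), with 0 of 9 passed by limma and 4 at an unadjusted p under 0.05. With an estimated correlation no list was called here: adjusted p = 0.174 for cartilage, 0.368 for bone, 0.174 for tendon, 0.174 for mesenchyme and 0.0707 for maxilla and palate genes. It was 0.178 for Wnt response, 0.212 for TGF-beta target, 0.457 for osteoclast, 0.554 for brain, eye and olfactory and 0.174 for mandibular genes. In mutant array 3 of this region the brain, eye and olfactory genes lay lower than in the other 2 arrays by a median of -1.37, bone genes higher by 0.45, muscle genes by 1.93 and epithelial genes by 0.83. Without that array the brain, eye and olfactory call ended (-0.24, adjusted p = 0.583) and the medians were -1.87 for cartilage and -0.21 for TGF-beta targets, and with both mutant maxilla arrays numbered 3 left out the epithelial list passed (0.17, 0.0427). Without control 1 the TGF-beta target median was -0.21 and the mandibular call ended (-0.35, 0.0662). Without control 3 the median was -0.18 for TGF-beta targets, and the calls of brain, eye and olfactory genes (-0.51, 0.0834) and mandibular genes (-0.28, 0.0505) ended. The call of osteoclast genes ended without mutant 1 (-0.50, 0.0569) and that of mandibular genes without mutant 2 (-0.22, 0.0726).

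**Figure D4:**
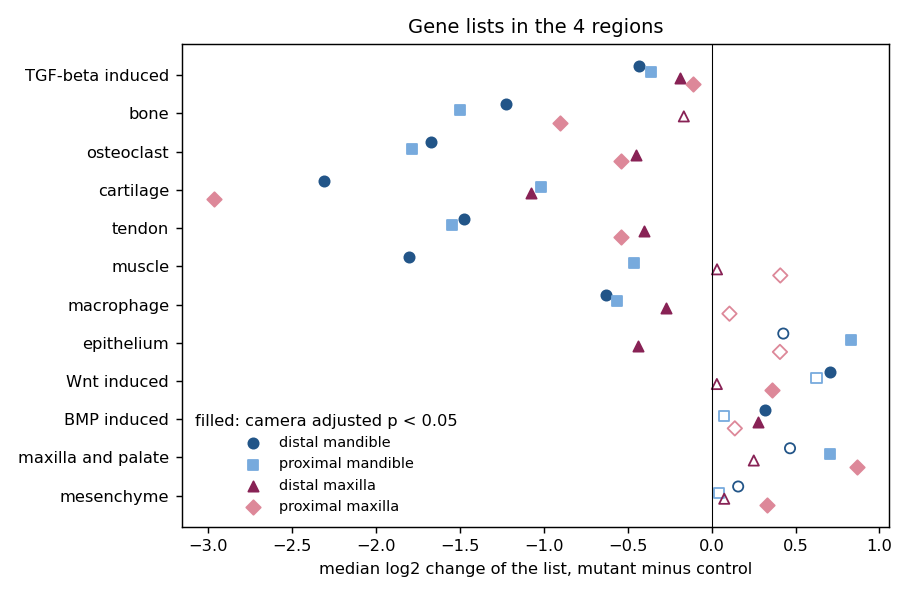
Median log2 change, mutant minus control (horizontal axis), of 12 gene lists (vertical axis) by region (shapes). Filled symbols passed camera with the preset correlation. Cartilage genes ranged from -1.02 in the proximal mandible to -2.97 in the proximal maxilla.

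The jaw interaction was the genotype effect in the mandible, mean of both ends, minus that in the maxilla. Bpifa1 went from 12.55 to 8.47 in the distal and from 12.37 to 9.26 in the proximal maxilla and stayed between 4.71 and 4.85 in the mandible (interaction 3.60 ± 0.58, SE, 3 arrays per group, adjusted p = 0.00105). The interaction was 3.09 ± 0.54 for Dynlrb2, a dynein light chain (0.00211), 2.89 ± 0.47 for Deup1 (0.00106), 2.49 ± 0.47 for Aldh1a1 (0.00334) and 2.39 ± 0.57 for Hoatz, a gene of motile cilia (0.0162). In the control mandible these 5 genes lay at 3.92 to 5.74, under the filter level, so a fall could not be seen there. Atp1b4 went from 9.61 to 5.58 in the distal and from 9.11 to 5.46 in the proximal mandible (-3.36 ± 0.41, 0.000137). Myh8 (-3.25 ± 0.73, 0.0112), Ttn (-3.06 ± 0.78, 0.0224, with 5 of its 6 probe sets of that sign), Tceal7 (-3.00 ± 0.66, 0.00964) and Ldb3, a Z-disc gene (-3.00 ± 0.61, 0.00554), also had a lower change in the mandible, and these 5 lay at 4.61 to 6.13 in the control distal maxilla, likewise under that level. In total 942 genes passed, 341 with a higher and 601 with a lower change in the mandible. Of these, 144 had a control mean under 6.33 in at least 1 region, and 101 in both ends of a jaw. The count was 579 without control distal mandible array 3, and 1522 with the replicate number as a fixed block or 1704 as a random block within genotype.

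Of 25 muscle genes, 6 had a lower change in the mandible than in the maxilla (11 adjusted over the list alone, median -1.44, camera adjusted p = 9.95e-08), such as Ckm (-2.57 ± 0.41). Tendon genes had 4 of 10 lower (7 adjusted over the list alone, median -0.68, 7.04e-07), such as Thbs4 (-2.99 ± 0.37). Osteoclast genes had 3 of 7 lower (5 adjusted over the list alone, median -1.17, 3.19e-05), such as Atp6v0d2 (-1.99 ± 0.24). These 3 had adjusted p = 0.398, 0.328 and 0.328 with an estimated correlation. Bone genes had 4 of 15 lower (7 adjusted over the list alone, median -0.91, 4.66e-05). Macrophage genes had 5 of 14 lower (6 adjusted over the list alone, median -0.42, 4.66e-05), such as Cd68 (-1.32 ± 0.24). Endothelial genes had 3 of 12 lower (5 adjusted over the list alone, median -0.27, 0.000667), such as the angiopoietin receptor Tek (-0.68 ± 0.16). TGF-beta pathway genes had 3 of 14 lower (5 adjusted over the list alone, median -0.10, 0.028). Each of these 4 had adjusted p = 0.398 with an estimated correlation. Hedgehog response genes shifted by -0.62 (0.00896, and adjusted p = 0.398 with an estimated correlation), with 0 of 5 passed by limma, 3 adjusted over the list alone and 3 at an unadjusted p under 0.05. Epithelial genes had 3 of 19 with a higher change in the mandible (4 adjusted over the list alone, median 0.44, 0.000178), such as Esrp1 (1.05 ± 0.17). Wnt response genes had 5 of 11 higher and 1 lower (6 and 3 adjusted over the list alone, median 0.30, 0.0486). Both had adjusted p = 0.398 with an estimated correlation. Brain, eye and olfactory genes had 1 of 8 higher (1 adjusted over the list alone, median 0.55, 0.0304, and adjusted p = 0.494 with an estimated correlation), the homeobox gene Emx2 (2.37 ± 0.33). Without both mutant maxilla arrays numbered 3, low in those genes and high in bone and muscle genes, their median was -0.049 (adjusted p = 0.79). The median was then -0.80 for muscle (3 members called), -0.48 for bone (0 called, against 4), -0.36 for hedgehog response (0.047), 0.45 for Wnt response (0.00463) and -0.068 for TGF-beta pathway genes (0.0535). The pathway call also ended without mutant proximal mandible 2 (-0.095, 0.0506) or mutant distal maxilla 3 (-0.075, 0.0514). That of brain, eye and olfactory genes ended without control proximal maxilla 3, mutant distal mandible 3 or mutant proximal mandible 1 (0.46 to 0.53, up to 0.0592), mutant distal maxilla 3 (0.28, 0.0792) or mutant proximal maxilla 3 (0.11, 0.232). The Wnt call ended without any 1 of 12 arrays (median 0.25 to 0.35, adjusted p from 0.0529 to 0.12).

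The end interaction was the distal genotype effect, mean of both jaws, minus the proximal one. Tmem132c went from 8.38 to 10.13 in the proximal mandible and from 8.0 to 9.63 in the proximal maxilla. Distally it went from 9.31 to 10.45 in the mandible and from 10 to 9.8 in the maxilla (interaction -1.22 ± 0.17, SE, 3 arrays per group, adjusted p = 0.00873). Krt1 (-2.67 ± 0.41, 0.0177), the basal keratin Krt15 (-1.99 ± 0.38, 0.048), Twist2 (-1.71 ± 0.29, 0.0211) and the protease Corin (-1.45 ± 0.24, 0.0211) had lower changes distally. Krt1 was at 11.94 to 13.32 in the distal and 7.84 to 8.42 in the proximal control maxilla. The mutant proximal maxilla lay between (9.95 to 11.68), as distal tissue there could give, untested. The Wnt antagonist Dkk1 (1.28 ± 0.22, 0.0211), Klhl14 (1.25 ± 0.23, 0.0455), Lmo7 (0.67 ± 0.13, 0.048), Pxdc1 (0.51 ± 0.10, 0.048) and the ketone body enzyme Bdh1 (0.47 ± 0.08, 0.031) had higher changes distally. In total 16 genes passed, 6 higher and 10 lower, against 48 with the replicate number as a fixed and 67 as a random block, 30 with array weights, and 8 to 10 with no filter, other uses of the probe sets, no trend or the sex score. Of the named genes, Tmem132c passed without any single array. Calls ended for Krt1 without mutant distal mandible 2 (-2.62, adjusted p = 0.0513) and for Corin without control proximal mandible 2, control distal maxilla 1 or mutant distal mandible 2 (-1.45 to -1.32, adjusted p up to 0.0596). The call of Twist2 ended without control distal mandible 1, control proximal mandible 2, control distal maxilla 3 or mutant distal mandible 2 (-1.69 to -1.63, up to 0.0598). That of Dkk1 ended without any 1 of 5 arrays (1.20 to 1.26, up to 0.0652). The calls of Klhl14, Lmo7, Pxdc1, Bdh1 and Krt15 ended without any 1 of 15, 20, 17, 11 and 19 of the 24 arrays, with adjusted p of at most 0.105, 0.123, 0.117, 0.0781 and 0.117, and under some other settings (up to 0.113). The count itself was 1 to 10 without any 1 control mandible array, control distal maxilla 1 or 3, mutant distal mandible 1 or 2, mutant proximal mandible 1, or mutant distal maxilla 1 or 2, and 32, 28 and 42 without control distal maxilla 2, mutant proximal mandible 3 and mutant distal maxilla 3. It was 49 without both mutant maxilla arrays numbered 3.

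Epithelial genes had the largest shift between the ends among the lists with a called member, a lower change distally (median -0.96, camera adjusted p = 1.53e-11; 1 of 19 passed and 10 adjusted over the list alone, and adjusted p = 0.15 with an estimated correlation). Cranial mesenchyme genes shifted by -0.17 (0.00535; 1 of 11 passed and 1 adjusted over the list alone, and adjusted p = 0.304 with an estimated correlation). In the other 6 lists limma passed 0 members. Maxilla and palate genes shifted by -0.68 (0.000139; 3 of 11 adjusted over the list alone, 5 at an unadjusted p under 0.05). Muscle genes shifted by -1.04 (2.09e-08; 3 of 25 at an unadjusted p under 0.05) and macrophage genes by -0.29 (0.00203; 0 of 14 at an unadjusted p under 0.05). With an estimated correlation these 3 had adjusted p = 0.108, 0.551 and 0.758. BMP response genes shifted by 0.27 (0.000139; 4 of 11 adjusted over the list alone, 5 at an unadjusted p under 0.05). Hypoxia genes shifted by 0.15 (0.000572; 6 of 12 adjusted over the list alone, 6 at an unadjusted p under 0.05) and lipid genes by -0.21 (0.00582; 1 of 6 adjusted over the list alone, 2 at an unadjusted p under 0.05). These 3 had adjusted p = 0.239, 0.15 and 0.237 with an estimated correlation. Without both mutant maxilla arrays numbered 3 the median of maxilla and palate genes was -0.42. Without mutant distal mandible array 2 the medians were -0.69 for muscle and -0.19 for macrophage genes (adjusted p = 0.0462). BMP response was at 0.18 without control proximal mandible 2 and 0.16 without control distal maxilla 3, and mesenchyme at -0.093 without mutant distal maxilla 2 and -0.096 without mutant proximal maxilla 3.

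In controls alone, mandible was compared with maxilla, over the mean of both ends. Hand2, the transcription factor of the mandibular arch, was higher in the mandible by 4.79 ± 0.25 (SE, 6 arrays per jaw, adjusted p = 3.34e-10), with levels of 12.46 and 9.68 in the distal and proximal mandible and 5.52 and 7.04 in the maxilla. The sarcomere genes Ttn (3.88 ± 0.55, 5 of 6 probe sets of that sign), Myh8 (3.79 ± 0.52), Tnnc2 (3.70 ± 0.53), Myh3 (3.54 ± 0.55) and Myom2 (3.41 ± 0.48), together with Tceal7 (3.58 ± 0.47), Atp1b4 (3.39 ± 0.29), the tendon gene Thbs4 (3.56 ± 0.26) and Mmp13 (3.36 ± 1.14, 0.0276), were higher. Bpifa1 was lower in the mandible (-7.69 ± 0.41, 3.34e-10). The brain and eye factors Otx2 (-5.67 ± 0.67) and Lhx2 (-5.20 ± 0.38), the neurogenic factors Insm1 (-5.10 ± 0.56) and Neurod1 (-4.74 ± 0.63), the olfactory factor Fezf1 (-4.80 ± 0.47), Fstl5 (-4.99 ± 0.50), Dynlrb2 (-4.89 ± 0.38) and the sulfotransferases Sult1d1 (-4.91 ± 0.70) and Sult1e1 (-4.84 ± 0.69) were lower too, and all 10 lay under the filter level in the mandible. In total 4843 genes differed, 2322 higher and 2521 lower in the mandible. The call of Mmp13 ended without control distal mandible 3, distal maxilla 2 or proximal maxilla 1 or 2 (2.74 to 3.30, adjusted p from 0.0514 to 0.08).

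Genes of mandibular identity had 8 of 9 higher in the mandible (8 adjusted over the list alone, median 1.10, camera adjusted p = 8.36e-07), and this call held with an estimated correlation (adjusted p = 0.00141). Pitx1 was at 2.21 ± 0.14. Muscle genes had 23 of 25 higher and 1 lower (24 and 1 adjusted over the list alone, median 2.72, 1.21e-10). Bone genes had 13 of 15 higher (14 adjusted over the list alone, median 1.45, 2.58e-06). Osteoclast genes had 6 of 7 higher (6 adjusted over the list alone, median 1.5, 1.66e-05). Tendon genes had 7 of 10 higher (8 adjusted over the list alone, median 0.83, 8.24e-05). In these 4 lists, Ckm was at 2.75 ± 0.29, the osteoblast factor Sp7 at 1.49 ± 0.20, Atp6v0d2 at 2.51 ± 0.17 and Mkx at 1.36 ± 0.19. Tooth genes had 13 of 17 higher and 1 lower (the same numbers adjusted over the list alone, median 0.81, 6.42e-05). Hedgehog response genes had 4 of 5 higher (5 adjusted over the list alone, median 0.80, 0.00527). Distal jaw genes had 4 of 6 higher (4 adjusted over the list alone, median 0.51, 0.00449). In these 3 lists, the activin subunit Inhba was at 0.97 ± 0.12, Foxf1 at 1.98 ± 0.33 and Msx2 at 0.59 ± 0.16. Genes of brain, eye and olfactory tissue had 7 of 8 lower (7 adjusted over the list alone, median -2.48, 5.74e-06). Neuron genes had 8 of 11 lower (8 adjusted over the list alone, median -2.30, 5.5e-06). Glia genes had 6 of 7 lower (6 adjusted over the list alone, median -0.50, 0.000453). In these 3 lists, Pax6 was at -3.08 ± 0.31, Stmn2 at -2.85 ± 0.28 and Sox10 at -0.80 ± 0.11. With an estimated correlation none of these 10 lists was called: adjusted p = 0.272 for muscle, 0.251 for bone, 0.169 for osteoclast, 0.183 for tendon and 0.214 for tooth genes. It was 0.272 for hedgehog response, 0.105 for distal jaw, 0.169 for brain, eye and olfactory, 0.183 for neuron and 0.183 for glia genes. Smaller shifts were those of proximal jaw genes (1.43, 0.0394) and epithelium (-0.29, 0.0358), with adjusted p = 0.169 and 0.488 with an estimated correlation. Those of endothelium (0.20), TGF-beta targets (0.14) and proliferation (0.10) each had 0.0394, with adjusted p = 0.455, 0.304 and 0.538 with an estimated correlation. Members called were 7 of 10 higher and 3 lower for proximal jaw genes, 8 of 19 lower and 2 higher for epithelium (9 and 5 adjusted over the list alone), and 6 of 12 higher and 1 lower for endothelium. They were 7 of 17 higher and 2 lower for TGF-beta targets and 5 of 19 higher for proliferation, and apart from epithelium these numbers were the same adjusted over the list alone.

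Of those 5 smaller calls, that of proximal jaw genes ended without any 1 of 6 of the 12 control arrays (1.30 to 1.44, adjusted p from 0.0507 to 0.0682). Epithelium ended without proximal mandible 2 (-0.19, 0.0667), distal maxilla 3 (-0.13, 0.14), or proximal maxilla 1 (-0.27, 0.0631) or 3 (-0.16, 0.0632), and its median was -0.47 without proximal maxilla 2. Endothelium ended without any 1 of 5 arrays (0.17 to 0.20, 0.0577 to 0.0964). TGF-beta targets ended without distal maxilla 3 (0.062, 0.0964) or proximal maxilla 1 (0.094, 0.0631), with medians of 0.096 without proximal mandible 3 and 0.092 without proximal maxilla 3. Proliferation ended without any 1 of 6 arrays (0.082 to 0.10, 0.0554 to 0.0839). The median of glia genes, which kept their call, was -0.84 without distal maxilla 3.

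Within the control mandible, Alx1, a homeobox gene of the frontonasal skeleton, was higher distally by 4.6 ± 0.35 (SE, n = 3 per end, 24.3-fold, adjusted p = 2.3e-07), from 7.14 ± 0.14 to 11.75 ± 0.09 (SD). The LIM homeobox gene Isl1 (3.39 ± 0.40), the secreted Wnt modulator Sfrp4 (3.17 ± 0.46), Them5 (3.11 ± 0.54) and the neuropeptide receptor gene Qrfpr (3.01 ± 0.12) were higher distally too. Crh, corticotropin releasing hormone (-3.41 ± 0.95, 0.0397), the nuclear receptor Nr2f1 (-3.02 ± 0.34), Shisa3 (-2.68 ± 0.42), Sim2 (-2.68 ± 0.54) and Barx1, a homeobox gene of the proximal jaw and molars (-2.49 ± 0.36), were lower distally. In total 760 genes differed, 406 higher and 354 lower distally, and 1156 with the replicate number as a fixed block, 1265 with it as a random block within genotype, 2547 with array weights or 1870 with only the arrays compared. The count was 394 and 362 without distal arrays 1 and 2, and 452, 416 and 465 without proximal arrays 1, 2 and 3. The call of Crh ended without any 1 of the 6 arrays (-3.51 to -3.33, adjusted p from 0.0858 to 0.131), with the stricter filter (0.0568) or with robust priors (0.0525).

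Epithelial genes had 13 of 19 members higher in the distal mandible (18 adjusted over the list alone, median 1.23, camera adjusted p = 2.39e-19). Distal jaw genes had 3 of 6 higher (3 adjusted over the list alone, median 0.51, 9.45e-06), with Hand2 at 2.77 ± 0.36. Both calls held with an estimated correlation (adjusted p = 0.0389 and 0.00526). Wnt response genes had 5 of 11 higher and 1 lower (6 and 1 adjusted over the list alone, median 0.30, 0.000528), with Lef1 at 0.69 ± 0.12 and the antagonist Dkk1 at -1.43 ± 0.22. Tooth genes had 4 of 17 higher and 1 lower (6 and 2 adjusted over the list alone, median 0.29, 0.0138), with Inhba at 0.92 ± 0.17. Cranial mesenchyme genes had 1 of 11 higher, Alx1 (2 adjusted over the list alone, median 0.12, 0.0146). Bone genes had 2 of 15 lower distally (5 adjusted over the list alone, median -0.64, 0.000528). Macrophage genes shifted by -0.30 (0.0138), with 0 of 14 passed by limma and 3 at an unadjusted p under 0.05. The last 5 had adjusted p = 0.165, 0.669, 0.526, 0.669 and 0.717 with an estimated correlation. Without distal array 2 the macrophage call ended (-0.23, adjusted p = 0.0689) and the mesenchyme median was 0.068 (0.0273).

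Within the control maxilla, Them5 was higher distally by 5.35 ± 0.54 (SE, n = 3 per end, adjusted p = 2.62e-06). So were the cornified envelope gene Sprr1a, by 4.98 ± 0.45 (7.5e-07), Dynap, by 4.93 ± 0.47 (1.32e-06), the desmosomal cadherin Dsg1a, by 4.79 ± 0.46 (1.74e-06) and Sdr16c6, by 4.77 ± 0.57 (1.62e-05). The sarcomere genes Tnnc2 (-3.51 ± 0.75, 0.00438), Myh8 (-3.35 ± 0.73, 0.00514), Ttn (-3.33 ± 0.78, 0.00795) and Myh3 (-3.29 ± 0.78, 0.00919), and Shisa3 (-3.14 ± 0.42, 5.24e-05), were lower distally. In total 1518 genes differed, 683 higher and 835 lower distally (45% higher), and after quantile normalization of all arrays 823 were higher and 770 lower (51.7%). The count was 2292 with the random block, 841 with only the arrays compared, 699 without distal array 3, 870 without proximal 1 and 999 without proximal 2, and without proximal 2 the calls of Ttn (-2.63, adjusted p = 0.0558) and Myh3 (-2.61, 0.0613) ended.

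Of 19 epithelial genes, 14 were higher in the distal maxilla (15 adjusted over the list alone, median 2.17, camera adjusted p = 1.93e-15), such as Krt6a (4.67 ± 0.51). Wnt response genes had 7 of 11 higher (9 adjusted over the list alone, median 0.62, 1.15e-08), such as Apcdd1 (2.03 ± 0.18). Immediate early genes had 4 of 10 higher and 2 lower (6 and 2 adjusted over the list alone, median 0.41, 0.000436), such as the heat shock gene Hspa1b (2.05 ± 0.32). As that list was written for genes that rise during tissue handling, its shift may reflect handling of the pieces, which was not tested. Proximal jaw genes had 5 of 10 lower (7 adjusted over the list alone, median -1.38, 0.000271), such as Pitx1 (-1.56 ± 0.19). These 4 calls held with an estimated correlation, with adjusted p = 0.0435 for epithelium, 0.0132 for Wnt response, 0.0435 for immediate early genes and 0.0132 for proximal jaw genes. Tooth genes had 8 of 17 higher and 1 lower (9 and 2 adjusted over the list alone, median 0.54, 0.000188), such as Sostdc1 (2.38 ± 0.27). Cranial mesenchyme genes had 3 of 11 higher (3 adjusted over the list alone, median 0.078, 0.0013), such as Twist2 (2.57 ± 0.29). Distal jaw genes had 4 of 6 higher and 1 lower (4 and 1 adjusted over the list alone, median 0.46, 0.00912), such as Msx2 (1.5 ± 0.23). These 3 had adjusted p = 0.277, 0.221 and 0.0682 with an estimated correlation. Muscle genes had 10 of 25 lower and 1 higher (13 and 1 adjusted over the list alone, median -1.37, 1.01e-05). Neuron genes had 3 of 11 lower (10 adjusted over the list alone, median -1.35, 6.78e-05), such as the neurofilament Nefl (-3.04 ± 0.62). Endothelial genes had 3 of 12 lower (10 adjusted over the list alone, median -0.28, 0.000256). Cartilage genes had 1 of 19 lower (1 adjusted over the list alone, median -1.15, 0.000436). The last 4 had adjusted p = 0.576, 0.277, 0.278 and 0.576 with an estimated correlation. Without distal array 3 the medians were -0.33 for cartilage (adjusted p = 0.046) and 0.16 for mesenchyme, which was at 0.12 without proximal 3, and that of muscle was -0.87 without proximal 2 (0.0059).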

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

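Tests of explanations and counts of other splits in this part were set up only after the results were seen, while the interaction tests were planned.

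Differences of the genotype effect between the jaws were called for 942 genes. Positive values mean a higher change in the mandible. The named genes were Bpifa1 (3.604), Dynlrb2 (3.089), Deup1 (2.893), Aldh1a1 (2.488), Hoatz (2.393), Atp1b4 (-3.363), Myh8 (-3.249), Ttn (-3.061), Tceal7 (-2.999) and Ldb3 (-2.998). The lists were TGF-beta pathway (-0.1), Wnt response (0.295), hedgehog response (-0.617), bone (-0.907), osteoclast (-1.168), muscle (-1.442), tendon (-0.676), epithelium (0.441), endothelium (-0.274), macrophage (-0.419) and brain, eye and olfactory genes (0.548). With the arrays of a replicate number kept together there are 10 splits, too few for a share under 0.05, and the highest other gave 20.

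Differences of the genotype effect between the ends were called for 16 genes, where positive values mean a higher change distally. The named genes were Dkk1 (1.281), Klhl14 (1.254), Lmo7 (0.668), Pxdc1 (0.508), Bdh1 (0.466), Krt1 (-2.667), Krt15 (-1.994), Twist2 (-1.706), Corin (-1.447) and Tmem132c (-1.221). The lists were BMP response (0.265), muscle (-1.036), epithelium (-0.96), macrophage (-0.288), cranial mesenchyme (-0.17), maxilla and palate (-0.679), hypoxia (0.146) and lipid genes (-0.205). With the numbers kept together, the highest other of 10 splits gave 2, again too few splits for a share under 0.05.

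Probe sets without a gene name were outside the comparisons of genes. Of 3248 tested, limma called 103 in the distal mandible, 5 in the distal maxilla, 189 in the proximal mandible, 29 in the proximal maxilla, 504 in the mean effect, 60 in the jaw interaction, 538 between the control jaws, and 38 and 114 between the ends of the control mandible and maxilla.

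For the other counts, 3 arrays against 3 give 10 splits, which cannot reach a share under 0.05. The real and highest other counts were 2231 and 0 in the distal mandible, 413 and 279 in the distal maxilla, 2777 and 1 in the proximal mandible, 1470 and 6 in the proximal maxilla, 760 and 0 between the ends of the control mandible, and 1518 and 3 in the control maxilla. The 279 came from control array 2 with mutants 1 and 2 against the rest, and of the 4 splits that part all numbered pairs the highest other gave 0 in the distal maxilla. Arrays of a number share their sex pattern in the 4 regions and were kept together in splits over several regions. For the mean genotype effect 5655 then stood against a highest other of 717 in 10 splits, and for mandible against maxilla 4843 against 0 in 4 splits, which cannot reach a share under 0.05 either. In 100 splits of single arrays, which take these as independent, the highest others were 56 and 2624, and 110 and 3 for the jaw and end interactions.

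The fall of cartilage and bone genes in the mutant could come from pieces that held tissue of other regions or from the sex makeup of the arrays. A mixture of the 4 regions keeps each gene at or above the lowest control region. The median of 34 bone and cartilage genes against that level was -1.223 in the mutant distal mandible (jackknife SE over arrays 0.196, 27 of 34 below) and -0.97 in the proximal maxilla (0.412, 30 of 34), both beyond 2 SE, which argues against such a mixture there. In the distal maxilla (-0.368, 0.364, 23 of 34) and proximal mandible (-0.239, 0.295, 20 of 34) the median was within 2 SE, with array 3 above 0, so it cannot be told apart there. With the sex score as a covariate the medians in the mean effect were -1.873 for cartilage and -1.009 for bone, which argues against sex, and an effect of the genotype or a delay in the mutant stays open, untested.

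The fall of muscle genes in the mutant distal mandible could come from maxillary tissue in those pieces or from less muscle. Hand2, at 12.46 in the control distal mandible and 5.52 and 7.04 in the control maxilla, changed by 0.579 ± 0.36, which argues against maxillary tissue. The mean of 16 contractile genes minus that of 6 precursor genes was 0.56 to 0.67 in the mutant arrays and 1.95 to 2.37 in their controls, but it also falls with the muscle signal in controls, to -0.25 to 0.1 in the distal maxilla. Against the control array nearest in the contractile mean, the mutant arrays lay at -0.89, 0.45 and -0.9, and with single maxilla arrays as the nearest ones, less muscle of the same kind cannot be told apart from a change in the muscle. An effect of the genotype on the muscle stays open, untested.

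The mutant maxilla arrays numbered 3 correlated best with mutant mandible arrays, but Hand2 in them differed from the lowest mandible array of either end by -2.39 (distal) and -2.65 (proximal), which argues against mandible arrays. With no background taken off, Hand2 allowed up to 19.1% of mandible tissue in the distal and 15.9% in the proximal array, above the bound of 10%, so mixing cannot be told apart. Genes of brain, eye and olfactory tissue differed from the mean of the other 2 arrays by a median of -1.37 in the proximal array, as less nasal, olfactory or neural tissue could give, and by -0.98 in the distal one, just short of the bound of -1. In an olfactory list chosen afterwards 16 of 16 genes were lower in both (-2.45 proximal, -1.86 distal), so less such tissue stays open at both ends. No biological explanation was tested for these single arrays.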

How the results depend on the processing

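Only the alternative without both mutant maxilla arrays numbered 3 was chosen after the data were seen. The cause of each move below was not tested, except that leaving out arrays or fitting only the groups compared lowers the number of arrays, and a fold threshold lowers the number of genes.

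Counts of called genes that moved by over 1.5 times were as follows. With array weights they were 4268 in the distal mandible, 1194 in the distal maxilla, 30 in the end interaction and 2547 between the ends of the control mandible. With the replicate number as a fixed block they were 1087 in the distal maxilla, 2397 in the proximal maxilla, 1522 in the jaw interaction, 48 in the end interaction and 1156 in the control mandible, and as a random block within genotype 1704, 67, 1265 and 2292 in the jaw interaction, the end interaction, the control mandible and the control maxilla. Averaging the 4 regions of a number gave 2114 in the mean effect. The sex score gave 242 in the distal maxilla and 9 in the end interaction. Without both mutant maxilla arrays numbered 3 the counts were 1113 in the distal maxilla, 783 in the proximal maxilla and 49 in the end interaction. Only the arrays compared gave 23 in the distal maxilla, 320 in the proximal maxilla, 1870 in the control mandible and 841 in the control maxilla. The end interaction gave 9 with no filter, 8 with the mean of probe sets, 10 with each probe set on its own and 9 without a trend. Each probe set on its own gave 9168 in the mean effect and 7803 between the control jaws.

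With a log2 change of at least 1 the counts were 378 (69 higher), 74 (16), 348 (102) and 259 (77) in the distal mandible, distal maxilla, proximal mandible and proximal maxilla. They were 158 (28) in the mean effect, 206 (83) and 7 (2) in the jaw and end interactions, 790 (266) between the control jaws, and 216 (146) and 449 (246) in the control mandible and maxilla.

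Leaving out 1 array at a time gave 1243 to 1825 genes in the distal mandible, 47 to 750 in the distal maxilla, 1922 to 2751 in the proximal mandible, 615 to 1439 in the proximal maxilla, 5256 to 5755 in the mean effect, 579 to 1226 in the jaw interaction, 1 to 42 in the end interaction, 4290 to 4908 between the control jaws, 362 to 528 in the control mandible and 699 to 1782 in the control maxilla.

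Of 145 results for named genes, 135 were past the threshold and 100 of these kept their direction and call under every alternative. For fits without 1 array, those with the lowest and highest change and the highest p count here. Of 2097 comparisons with alternatives, 2005 kept both, 75 lost the call, 9 gained one and 8 changed sign. Those 8 concern Tgfb1 and Tgfb3 in the distal maxilla, which were not called. Tgfb1 (0.08) was at -0.055 with the mean of its probe sets, -0.11 with array weights, -0.233 without both mutant maxilla arrays numbered 3 and also without mutant distal maxilla 3 alone, and -0.019 without control distal maxilla 2, and reached 0.263 without mutant 2. Tgfb3 (0.077) was at -0.094 with array weights, -0.059 without both arrays numbered 3 and -0.07 without control distal maxilla 3, and reached 0.182 without mutant 2.

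Of 101 called lists, 7 kept their call with an estimated correlation and 84 kept it whichever 1 array was left out. Calls were kept by 98 with no filter, 96 after quantile normalization, 99 with the fixed block, 98 with the sex score and 98 without both mutant maxilla arrays numbered 3. Calls that ended, with their adjusted p, were with no filter those of macrophage genes in the distal maxilla (0.0872), Wnt response in the jaw interaction (0.0763) and proximal jaw genes between the control jaws (0.075). After quantile normalization they were brain, eye and olfactory genes in the proximal maxilla (0.0573) and the jaw interaction (0.0631), Wnt response there (0.0914), and TGF-beta targets (0.0598) and proliferation (0.0759) between the control jaws. With the sex score they were macrophage genes in the distal maxilla (0.0933), muscle in the proximal mandible (0.159) and Wnt response in the jaw interaction (0.0522), and with the fixed block epithelium (0.0597) and proximal jaw genes (0.0627) between the control jaws. Without both arrays numbered 3 the brain, eye and olfactory call in the proximal maxilla ended too (0.35), and 2 in the jaw interaction. For arrays the signal over background sets what can be seen, and genes near the filter level cannot show a fall.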

Other observations

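All tests in this part, on lists of ciliated, cornified, olfactory and muscle genes, were chosen after the results were seen, with unadjusted p-values. The lists hold genes already seen to change, such as Deup1, Dynlrb2 and Krt1, so the tests are not independent evidence.

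Genes of motile cilia were lower in the mutant distal maxilla, with 13 of 19 called and a median of -1.74 (camera p = 0.0117 with an estimated correlation), and in the proximal maxilla, with 12 called and a median of -1.35 (0.0446). In the jaw interaction 14 were called, with a median of 1.71 (0.0147). Without both mutant maxilla arrays numbered 3 the medians were -1.68 (13 called), -1.23 (5 called) and 1.52 (11 called). Many of these genes lay under the filter level in the control mandible, where no fall could be seen. In controls 16 of 19 were lower in the mandible (-1.95, 0.0308).

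Cornified epidermis genes were all higher in the distal than in the proximal control maxilla (15 of 15, median 4.4, p = 0.00117 with an estimated correlation). In the mutant they were higher in the proximal maxilla, with 8 of 15 called (1.20, 0.121). In the distal maxilla their median was -1.04 (0.0689), with 0 called by limma and 10 lower at an unadjusted p under 0.05, and 11 called lower (-1.53) without both mutant maxilla arrays numbered 3. The proximal maxilla then had 5 called (0.79). The end interaction had a median of -1.03 (0.0168), and -1.11 without these arrays (4 called). Of 16 olfactory genes, 15 were lower in the control mandible than in the control maxilla (-3.79, 0.0367). In the mutant distal mandible 11 of 16 contractile muscle genes were lower (-2.69, 0.0594), and of 8 precursor genes limma called 0 (-1.06, 0.215), with 4 lower and 1 higher at an unadjusted p under 0.05.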
